A study of Mus musculus with 2 samples.

How the data were processed

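MicroRNA sequencing libraries of tissue labelled layer of hippocampus, from 5xFAD heterozygous female mice, were analysed, 1 group with 2 biological replicates. Per the labels, libraries were made from total RNA for a small insert size range with a multiplexed miRNA protocol. The adapter-trimming document cited in the labels differs between the replicates, so trimming and replicate cannot be separated. The deposited files hold raw read counts per miRNA gene, in 3 columns: both strands, the gene strand and the opposite strand. Per the file notes deposited beside them, the assembly is mm10 and the annotation GENCODE M21. The aligner and counter are not given in the sources used here. Values were not normalized and replicates were not pooled by the authors, as far as the counts show: whole numbers with unequal totals.

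Gene-strand counts were the main values. The leading rows that name no gene stayed out of library sizes and tests. In replicate 1 they held 17.6% unmapped, 37.1% multi-mapped and 3.46% uniquely mapped reads outside miRNA genes, and in replicate 2 they held 20.5%, 37.5% and 4.61%. Gene-strand counts made up 41.9% and 37.4% of reads. Multi-mapped reads were not assigned to any gene, so counts of miRNAs with several near-identical genomic copies cannot be taken as their abundance. A shared 20-base stretch between annotated precursors (1084 genes) marked genes as uncertain, and genome-wide uniqueness was not analysed here. In the unstranded column, 15 genes with at least 100 gene-strand counts in both libraries had 0 counts, and some others that overlap a miRNA gene on the opposite strand, such as Mir129-2 with 8 and 7, had few. All 2202 gene IDs matched the reference annotation, which also gave coordinates and host genes.

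CPM is the count scaled to a total of 1000000 counts on miRNA genes, with mean and SD over 2 replicates, and single-library shares have 95% Wilson intervals. A gene was detected with at least 10 counts in each library and tested with at least 10 summed over both. A two-sided exact binomial test compared the count of replicate 2 out of both with the share expected from the library totals. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold ratio. Ratios are on the log2(CPM + 1) scale, which understates the change of low genes. P-values below 1e-300 were kept at that value. With 1 group a model of group means has nothing to compare, so edgeR gave only a common dispersion from an intercept-only fit, TMM library sizes and a negative binomial exact test at that dispersion. That test uses the library totals without TMM scaling and takes its dispersion from the same 2 libraries. Intervals of the correlation and dispersion came from 1000 and 100 bootstrap draws over genes.

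Before the data were examined, 18 gene lists (207 distinct symbols) and the rule for named genes were fixed. The rule took the 25 genes of highest mean CPM, the 10 with the largest absolute log2 ratio among those past the test with a mean of at least 100 CPM, and the 4 most abundant members of each list. Of the listed symbols 5 were found under a newer symbol and 2 were absent from the annotation. Other genes named were chosen after their values were seen. They are the list members past the test that are outside the rule and the remaining members of the Mir183 and Mir200 clusters. The Mir124a and let-7a loci, Mir203, Mir205 and Gm26117 were also chosen this way. The lists cover neurons, activity-regulated genes, Mir9, astrocytes, oligodendrocytes, microglia and leukocytes, endothelial and mural cells, erythroid cells, choroid plexus and ependyma, epithelial and neuroendocrine cells, sensory and pineal cells, Hox clusters, liver and muscle, pluripotency, let-7, miR-17-92, Dlk1-Dio3 and the Alzheimer's disease literature. Some lists share members. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. Random lists were drawn gene by gene, so the percentiles take genes of a common cluster as independent. The plan worded the list median as taken over detected members. It was computed over tested members, and the version with at least 10 counts in each library is printed wherever the difference moved a list out of the upper tail.

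Alternatives were unstranded counts, TMM and DESeq2 scaling, other count minimums, no fold threshold, the negative binomial model, other pseudocounts, other denominators and each replicate left out. Added after the data were seen were fits without genes sharing a 20-base stretch, without the epithelial and sensory lists and with Mir139 left out of the library totals. The comparison of replicate 2 with replicate 1 was tested on counts simulated with sampling noise only, over 513 genes. On the adjusted p alone, without the fold threshold, the exact test called 74 of 98 genes changed 2-fold and 93 of 95 changed 4-fold. Of the unchanged genes, 0 of 320 were past both thresholds. The real libraries differed by more than sampling noise, so the simulation does not give their rate of false calls. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.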

Results

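MicroRNA abundance was measured by small RNA sequencing in tissue labelled layer of hippocampus, from female mice heterozygous for the 5xFAD transgenes. 5xFAD is a mouse model of Alzheimer's disease that carries mutant human APP and PSEN1. The series held 1 group of 2 libraries, recorded as biological replicates 1 and 2, with no wild-type or other control group. The labels state the purpose only as an evaluation of RNA, so the data answer which microRNA (miRNA) genes the tissue held and how closely the libraries matched. The labels give the libraries separate biosamples under a single donor entry and no age. Whether they came from separate animals is therefore open, and the spread between them may be partly technical. Replicate 1 had 3819120 counts on miRNA genes among 9124801 reads, and replicate 2 had 3607727 among 9651512. Of the 2202 miRNA genes, 408 had at least 10 counts in each library and were taken as detected, while 1429 had no count in either. A gene at 0 could hold up to 0.786 CPM (counts scaled to a library total of 1000000) in replicate 1 and 0.832 in replicate 2, from 3 counts. Intervals and floors cover counting error only.

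Mir139, which lies in an intron of the phosphodiesterase gene Pde2a, had the most counts among reads that mapped to 1 locus, at 206537 ± 84265 CPM (SD, n = 2). Mirlet7b followed at 122477 ± 23685 CPM, then Mir744 at 53659 ± 3429, Mir127 at 49789 ± 1931 and Mirlet7i at 38759 ± 4919 CPM. Mir125a at 26328 ± 4344 CPM, Mir149 at 23283 ± 3421 and Mir132, a neuronal activity-regulated miRNA, at 12343 ± 4715 were also among the 25 most abundant genes. Reads that mapped to several loci were not assigned to genes, at 0.887 per gene count in replicate 1 and 1.00 in replicate 2, so this ranking leaves out miRNAs held mainly by such reads. Of these 25, 5 were let-7 genes and 4 were genes of the imprinted Dlk1-Dio3 region, and 24 were within 2-fold between the libraries. The exception was Mir22, at 4347 CPM in replicate 1 and 10659 CPM in replicate 2. With TMM library sizes 23 were within 2-fold: Mir22 was 1.96-fold apart, and Mir139 and Mir324 were past 2-fold, at log2 ratios of -1.18 and -1.19. The single most abundant gene took 26.6% of the counts in replicate 1 and 14.7% in replicate 2. The 10 most abundant took 61.1% ± 3.41 and the 25 most abundant 78.7% ± 2.71 (SD, n = 2).

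In mm10 coordinates with GENCODE M21 genes, Mir139 lies on chromosome 7 from 101475376 to 101475443. Mirlet7b lies on chromosome 15 from 85707319 to 85707403, in an exon of the non-coding transcript Lncppara. Mir744 lies in an intron of Map2k4 on chromosome 11, from 65734733 to 65734832. Mir127 lies on chromosome 12 from 109592846 to 109592915, opposite an exon of Rtl1. Of the 25 genes, 10 lay in an intron of a gene on the same strand, 9 overlapped an exon on the same strand and 3 overlapped no other gene. Mirlet7e and Mir191 overlap another miRNA gene on the opposite strand, and both had counts only where strand was used.

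**Figure D1:**
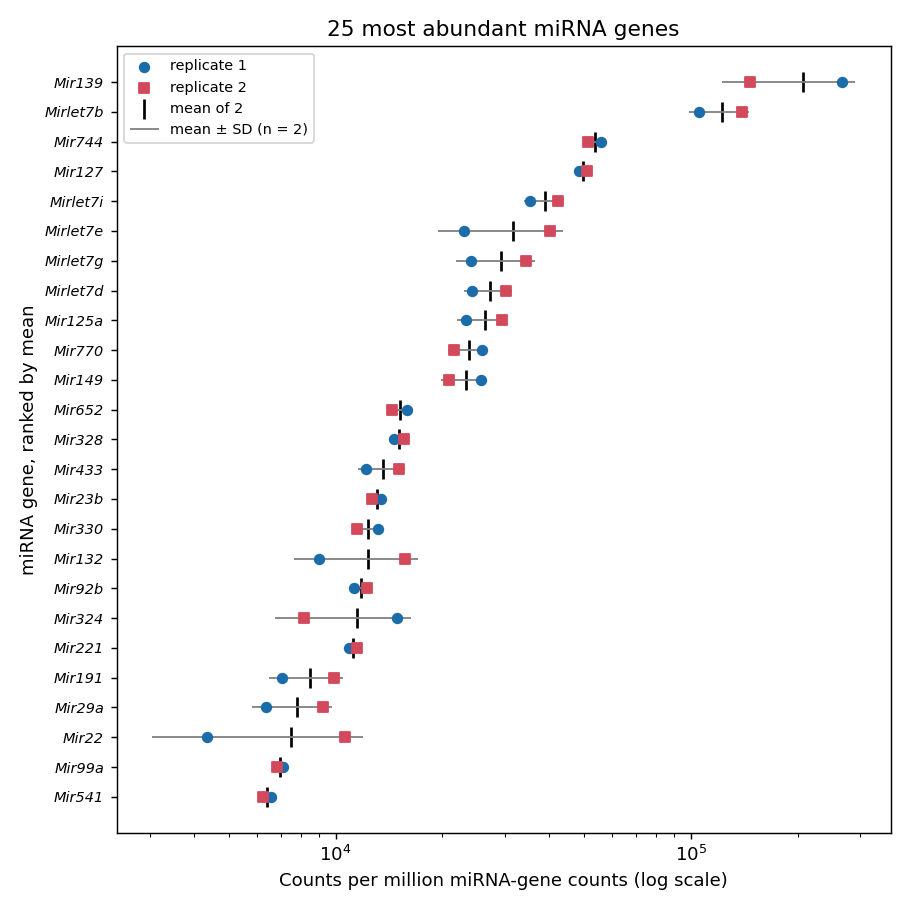
CPM on a log axis for the 25 most abundant miRNA genes, with circles for replicate 1, squares for replicate 2, a tick for the mean and a line for the mean ± SD (n = 2). Mir139 leads at 206537 CPM, and Mir22 is the gene of these 25 more than 2-fold apart against the library totals, while with TMM library sizes Mir139 and Mir324 are.

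The let-7 family, whose members accumulate as neurons and glia mature, held 21.5% of the counts in replicate 1 (95% Wilson interval 21.5 to 21.6) and 29.0% in replicate 2 (28.9 to 29.0), with all 12 annotated members detected. Among reads that mapped to 1 locus, Mirlet7b, Mirlet7i, Mirlet7e at 31563 ± 12151 CPM and Mirlet7g at 29158 ± 7267 had the most counts. Reads of let-7 members with several near-identical loci were left unassigned where they mapped to more than 1, so neither this order nor the family share can be taken as abundance. Only Mir98 was past the exact binomial test with a 2-fold difference, at 306 CPM in replicate 1 and 679 in replicate 2, and no member was with TMM library sizes. Genes of the Dlk1-Dio3 region, a maternally expressed miRNA cluster on chromosome 12 between 109563692 and 109747960, held 12.7% and 14.2% of the counts, and 49 of 59 were detected. Mir127, Mir770 at 23695 ± 2984 CPM, Mir433 at 13599 ± 2049 and Mir541 at 6409 ± 219 led the region. In this region 9 genes were higher in replicate 2 and none was lower, among them Mir379 (334 and 869 CPM) and Mir411 (1254 and 2766 CPM), whose counts are uncertain because it shares a 20-base stretch with another miRNA gene. With TMM library sizes 6 were higher, among them Mir379 but not Mir411. The median log2 ratio of its 51 tested members was 0.60, above 99.84% of random lists of matched expression, while the ratio of the summed counts was at percentile 44.56. Random lists were drawn gene by gene, so these percentiles take the clustered genes of the region as independent. The miR-17-92 family held 1.42% and 1.57%, led by Mir92b at 11764 ± 709 CPM and Mir93 at 1453 ± 69.1, with no gene past the test at 2-fold.

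MiRNA genes of neurons held 1.24% of the counts in replicate 1 (95% Wilson interval 1.23 to 1.25) and 1.68% in replicate 2 (1.66 to 1.69), and 12 of 15 were detected. Mir383 at 5805 ± 1469 CPM led this list, before Mir128-1 at 4360 ± 716, Mir129-2 at 1439 ± 106 and Mir137 at 1345 ± 517. Mir128-1 and Mir129-2 each share a 20-base stretch with another miRNA gene, so their counts are uncertain, as are those of Mir135a-2, Mir138-1, Mir138-2, Mir23a, Mir219a-2, Mir146 and Mir107. The 3 Mir124a loci, which encode the most neuron-restricted miRNA, and the 3 Mir9 loci together had only 74 counts in replicate 1 and 411 in replicate 2, and these 6 genes also share sequence with one another. Reads that mapped to several loci, 37.1% and 37.5% of all reads, were not assigned to genes, so these counts cannot be taken as the miRNAs' abundance. Among the neuronal genes, Mir135a-2 (6.81 and 27.7 CPM) and Mir124a-3 (2 and 11 counts), both uncertain for this reason, were higher in replicate 2, and with TMM library sizes Mir135a-2 was higher, Mir124a-3 was not past the test and Mir153 was lower. All 5 activity-regulated genes were detected, with 1.87% and 2.23% of the counts, led by Mir132 and by Mir138-1 at 3794 ± 1322, Mir138-2 at 3017 ± 1089 and Mir212 at 872 ± 122 CPM. None of them was past the test at 2-fold against the library totals, while Mir138-1 and Mir138-2 were lower in replicate 2 with TMM library sizes.

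Every glial and vascular list had detected members. The astrocyte list held 1.43% ± 0.103 of the counts (SD, n = 2), led by Mir29a at 7795 ± 1993 CPM and Mir23a at 5691 ± 1183, with all 8 members detected. The oligodendrocyte list held 0.396% and 0.330%, almost all of it on Mir219a-2 (2156 ± 260 CPM) and Mir338 (1465 ± 201 CPM), which promote oligodendrocyte maturation. Both overlap a miRNA gene on the opposite strand and had no count where strand was not used. Neither list had a gene past the test at 2-fold, except that the astrocyte list gene Mir193b was lower in replicate 2 with TMM library sizes. The microglia and leukocyte list held 0.241% and 0.407%, led by Mir150 at 2013 ± 945 CPM and Mir146 at 997 ± 190. The neutrophil and monocyte gene Mir223 was higher in replicate 2, with 18 and 237 counts. The endothelial and mural list held 0.224% and 0.413%. Its endothelial gene Mir126a was higher in replicate 2 (1047 and 2397 CPM), as was Mir214, at 21.5 and 276 CPM, but with TMM library sizes Mir126a was 1.83-fold higher and lost its call, while Mir214 was 9.93-fold higher. The erythroid list held 0.00204% and 0.00438%, with Mir451a at 11 and 37 counts.

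**Figure D2:**
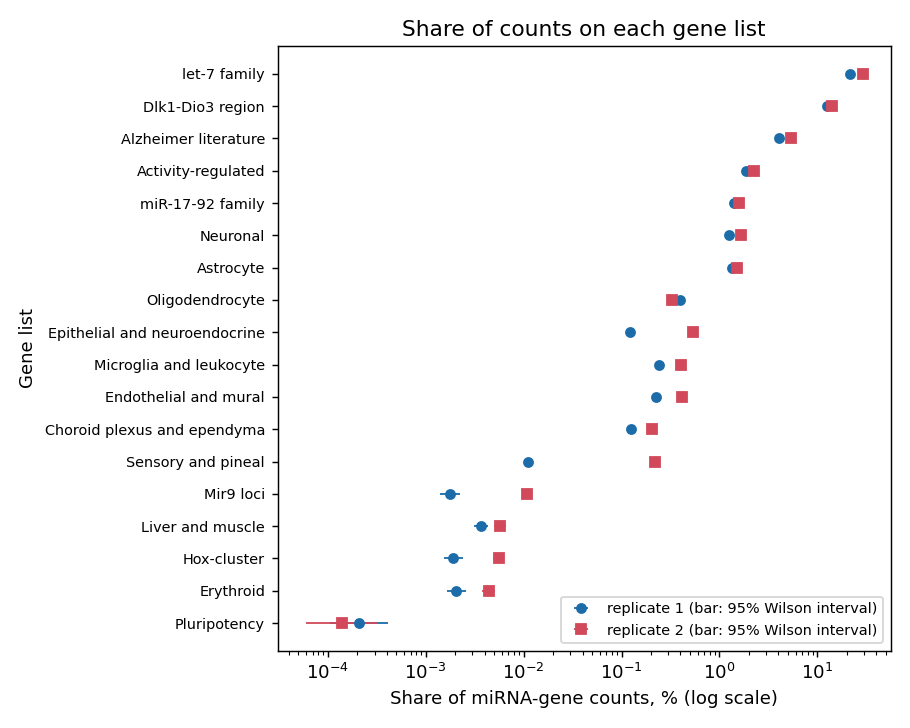
Share of miRNA-gene counts, in percent on a log axis, for the 18 fixed gene lists in replicate 1 (circles) and replicate 2 (squares), with 95% Wilson intervals as bars. The let-7 family holds the largest share, and the sensory and pineal list is 20.1-fold apart between the libraries.

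Across the 514 genes with at least 10 counts summed over both libraries, log2(CPM + 1) had a Pearson r of 0.970 (95% bootstrap interval over genes 0.963 to 0.978) and a Spearman rho of 0.949. These coefficients run across genes, which are not independent replicates. The libraries differed by more than sampling noise, with a chi-square of 311725 on 513 degrees of freedom. This argues against repeat deposits of a single library under the same processing. It does not cover a single library processed differently, and does not say whether the spread is biological or technical. The libraries were counted as 2 samples because the labels record them so. The labels cite a different adapter-trimming document for each library. The common biological coefficient of variation was 0.475 (95% bootstrap interval over genes 0.428 to 0.529). By a two-sided exact binomial test with Benjamini-Hochberg adjustment, which compares these libraries and not conditions, 92 genes differed at least 2-fold, 81 higher and 11 lower in replicate 2. The median gene was 0.30 higher in replicate 2 on the log2 scale, and the median was 0.01 with TMM library sizes, under which 55 genes were higher and 30 lower. With DESeq2 size factors 55 were higher and 32 lower. Mir185, in an intron of Tango2, was the named gene lowest in replicate 2 relative to replicate 1, at 1108 CPM in replicate 1 and 225 CPM in replicate 2. It was not past the negative binomial test at the common dispersion (adjusted p = 0.678, edgeR).

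The epithelial and neuroendocrine list and the sensory and pineal list had the highest median log2 ratios of the 17 lists with a tested member. The former held 0.123% of the counts in replicate 1 (95% Wilson interval 0.119 to 0.126) and 0.540% in replicate 2 (0.532 to 0.547), and 6 of its 7 genes were higher in replicate 2. The latter held 0.0110% (0.00997 to 0.0121) and 0.220% (0.215 to 0.225), and all 3 of its genes were higher. Mir183, a miRNA of sensory epithelia, photoreceptors and the pineal gland, was 26.6-fold higher, at 253 and 6458 counts, and Mir182 was 9.37-fold higher. Mir200b, Mir200c and Mir429, which maintain epithelial identity, were 23.5-fold, 17.5-fold and 14.7-fold higher. Mir375, a gene of endocrine cells, was 2.89-fold higher, while Mir7b was at 752 and 718 CPM (exact binomial test, adjusted p = 0.146). Median log2 ratios were 4.11 and 3.23, above 100% and 99.52% of random lists of matched expression. Most genes of these lists lie in clusters, while random lists were drawn gene by gene, so these percentiles take clustered genes as independent. The counts were the same with TMM or DESeq2 scaling, and the calls adjusted over the list alone equalled those over all genes in these and all other lists.

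Of these list genes, all but Mir375 and Mir7b lie in 3 clusters. Mir183, from 30169668 to 30169737 on chromosome 6, lies beside Mir96 and Mir182 and overlaps no other gene. Mir200b, on chromosome 4 from 156055681 to 156055750, lies in an intron of Ttll10 with Mir200a, and Mir429 follows. Mir200c, on chromosome 6 from 124718322 to 124718390, lies beside Mir141. The 8 cluster members were 5.79-fold to 26.6-fold higher in replicate 2 and took 0.0311% and 0.608% of the counts. With a negative binomial test at the common dispersion, 12 genes differed, all higher in replicate 2, and 6 of these were cluster members. That test used the library totals, under which the median gene was 0.30 higher in replicate 2. It was not run with TMM library sizes. Among the other genes with a mean of at least 100 CPM, Mir214, in an exon of Dnm3os, was 12.3-fold higher. Mir26a-2, which shares sequence with Mir26a-1 and is uncertain, was 18.1-fold higher. Below that mean, Gm26117, Mir223, Mir10b and Mir196b were also past the negative binomial test, Gm26117 at 10 and 237 counts. Mir1839 and Mir31 were 4.42-fold and 4.19-fold higher and were not past the negative binomial test (adjusted p = 0.863 and 0.902, edgeR). Of the cluster members, Mir182 and Mir96 were not past the negative binomial test either (adjusted p = 0.112 and 0.388, edgeR).

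**Figure D3:**
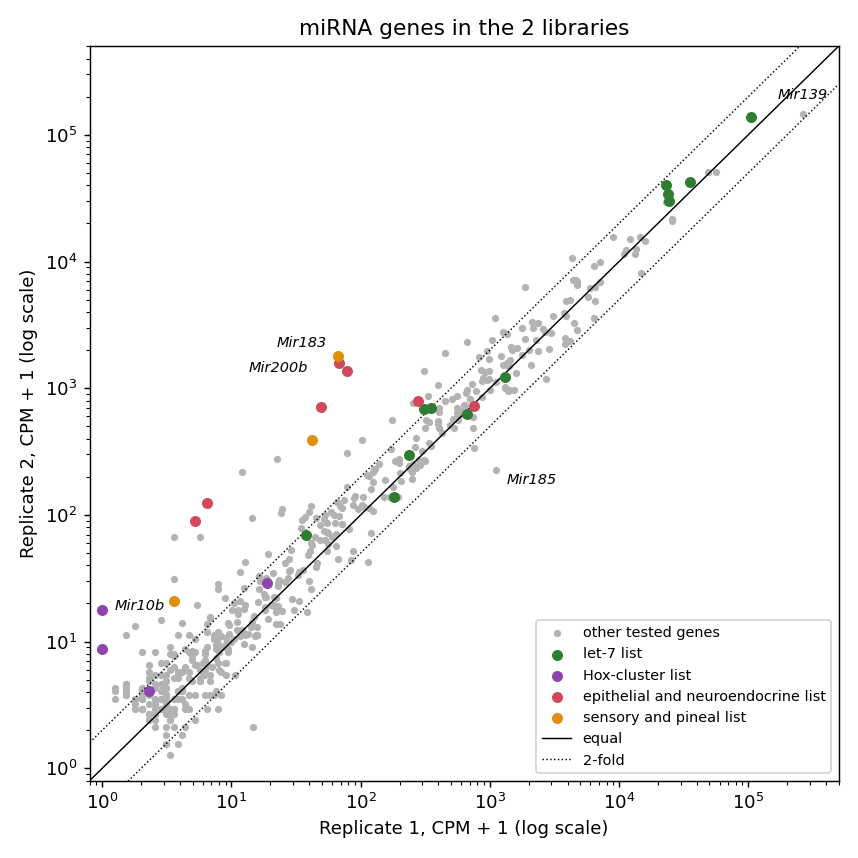
CPM + 1 in replicate 1 (x, log axis) and replicate 2 (y, log axis) for the tested miRNA genes, with a solid line at equality, dotted lines at 2-fold and colours for 4 lists. Genes of the epithelial and sensory lists sit above the 2-fold line apart from Mir7b, while the let-7 genes lie within 2-fold apart from Mir98, which is within it with TMM library sizes.

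The choroid plexus and ependymal list held 0.124% and 0.203% of the counts, and 4 of its 8 tested genes were higher in replicate 2. Mir1298, in an intron of the choroid plexus serotonin receptor gene Htr2c, stood at 77.2 and 305 CPM, and Mir764 from the same gene at 18.1 and 48.2. Its leading gene Mir204, in an intron of Trpm3, had 1171 ± 266 CPM and was not past 2-fold. The median log2 ratio was 1.11, above 99.45% of random lists, and 0.86, above 96.67%, with at least 10 counts in each library, while the ratio of the summed counts was at percentile 75.71. These percentiles take genes that lie together, such as Mir1298 and Mir764 in Htr2c, as independent. The Hox-cluster list, which marks hindbrain, spinal cord and trunk, held 0.00191% and 0.00554%. Mir10b, in introns of Hoxd3 and Hoxd4, had 0 and 60 counts, and Mir196b, in an exon of Hoxa9, had 0 and 28 counts. Set against 3 counts in replicate 1, they were 21.2-fold and 9.88-fold higher in replicate 2. These ratios use the library totals and take the replicate 2 counts as exact, so they are not lower bounds. Mir10a had 68 and 101 counts. The median log2 ratio of this list was 1.97, above 99.93% of random lists, and 0.62, at percentile 67.80, with at least 10 counts in each library, which leaves Mir10a alone. The Mir9 list had a median of 2.39, above 99.21% of random lists, and 2.71, at percentile 90.24, for Mir9-1 alone under the same minimum, while the ratio of the summed counts was at percentile 94.70.

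Liver and muscle genes held 0.00369% and 0.00574% of the counts, with Mir122 at 95 and 103 counts and Mir206 at 44 and 92. In that list 2 genes were higher in replicate 2, and Mir499 (1 and 12 counts) but not Mir206 was with TMM library sizes. The pluripotency list had 8 counts in replicate 1 and 5 in replicate 2, with no gene detected. Genes discussed in the Alzheimer's disease literature held 4.06% and 5.34%, and 23 of 28 were detected. Mir328 led at 15070 ± 676 CPM, with Mir132, Mir29a and Mir107 at 2331 ± 104 next. In that list 5 genes were higher in replicate 2, among them Mir298 at 662 and 2336 CPM. With TMM library sizes 4 were higher, Mir298 among them, and Mir153 was lower. The median log2 ratio was at percentile 63.01. With no control group, none of these levels shows an effect of the transgenes.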

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

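Of the tests in this part, the one on multi-mapped reads was fixed before its result was seen, and the tests on adapter bias, outside tissue, sampling noise, library composition and GC content were chosen afterwards. Signals in data outside the gene-strand counts were picked out because they exceeded what a count of 0 allows. Reads mapped to several loci made up 37.1% of reads in replicate 1 and 37.5% in replicate 2. Uniquely mapped reads outside miRNA genes made up 3.46% and 4.61%. Reads opposite to a miRNA gene with no miRNA gene on their own strand numbered 91 and 146.

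The Mir9 and Mir124a loci, expected to be abundant in brain, had few counts. The highest of the 6 loci in either library held 92.9 CPM, below the 1000 CPM set beforehand. A value above that bound would have argued against unassigned multi-mapped reads as the cause. A low value only restates the pattern, so this test does not decide the explanation. All 6 loci share a 20-base stretch with another miRNA gene, and multi-mapped reads were not assigned. The low counts therefore do not show that these miRNAs were scarce. Mirlet7a-1 had 903 and 1060 counts and Mirlet7a-2 had 693 and 499. Which miRNAs the multi-mapped reads hold was not analysed here, and no biological explanation was tested.

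The Mir183 and Mir200 cluster genes were higher in replicate 2. Counting error alone is argued against, since 8 of 8 members were past the exact binomial test adjusted over all 514 tested genes, but that test takes reads as independent molecules and does not cover duplication by PCR. Adapter or ligation sequence bias stays open: 0% of 10000 draws of 5 genes of matched expression reached the lowest log2 ratio of the 5 octamer classes, but these classes were picked for their ratios and some differ by only 1 base, and the trimming document differed with the replicate. RNA from tissue outside the forebrain may contribute, as a hypothesis. The ratio of the summed Hox-cluster counts between the libraries lay at percentile 98.17 of random lists, a result that rests on Mir10b and Mir196b. This test was chosen after the data were seen and holds none of the Mir183 and Mir200 genes, so it cannot tell where their RNA came from. Mir205 stood at 10 and 108 counts but Mir203 at 77 and 78. Differences between animals and carry-over between multiplexed libraries stay open and untested.

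More genes were higher than lower in replicate 2. Precursor GC content stays open. Across tested genes the log2 ratio fell as GC content rose (Spearman rho -0.19, two-sided permutation p = 0.0001, the smallest possible here). The permutation takes genes as independent, clustered ones included, so this p describes these libraries and not the spread between libraries. After a linear GC trend was removed 86.0% of calls were higher, against 88.0% before. That correction keeps the mean and left the median log2 ratio at 0.30, so it could not remove an overall shift. A different share of counts on Mir139 may account for part of the skew. Leaving Mir139 alone out of the totals shifts the scaling between the libraries by 0.22 on the log2 scale. Low genes shift by less, because 1 CPM is added before the ratio is taken. The median ratio goes from 0.30 to 0.11, and 72.7% of calls were higher. This shift follows by arithmetic from the Mir139 shares of 26.6% and 14.7%, so it does not show why they differ. The remainder was not explained, and no biological explanation was tested. TMM scaling, with 64.7% higher, centres the ratios whatever the cause and does not bear on it.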

How the results depend on the processing

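The settings without genes sharing a 20-base stretch, without the epithelial and sensory lists and with Mir139 left out of the library totals were chosen after seeing the data and gave 75 genes (67 higher, 8 lower), 83 genes (72 higher, 11 lower) and 88 genes (64 higher, 24 lower). None of the 10 genes named for their replicate ratio changed direction under the settings run for them. Smaller ratios did: of the 25 most abundant genes, 7 past the exact binomial test at any fold changed sign with TMM library sizes, such as Mir127, from a log2 ratio of 0.08 to -0.24, and Mirlet7i, from 0.26 to -0.06. Some list values did too: the activity-regulated median log2 ratio was 0.29 in the main analysis and -0.03 with TMM library sizes. Without the 3 most abundant genes the Dlk1-Dio3 share was 22.1% in replicate 1 and 21.4% in replicate 2, the astrocyte share 2.38% and 2.27% and the miR-17-92 share 2.48% and 2.37%, each the opposite order to the main analysis. The oligodendrocyte order also turned with unstranded counts, at 5.48e-05% and 5.94e-05%. These shares rest on 2 counts of Mir219a-1 in each library, so that order only follows the library totals. Detected genes numbered 626 at 1 count or more in each library. Genes differing between the libraries numbered 279 with no fold threshold and 12 with the negative binomial model, against 92 in the main test, because these settings drop the fold criterion or widen the error. With all mapped reads as the denominator, the listed genes held 23.9% of reads, the neuronal list 0.710%, let-7 12.3% and Dlk1-Dio3 6.54%. Without the 3 most abundant genes, one of which is Mirlet7b, the listed genes held 59.5%, the neuronal list 2.35% and Dlk1-Dio3 21.8%. The denominator itself sets these shifts. With at least 10 counts in each library, the median log2 ratio was 2.71 for the Mir9 list, 0.86 for the choroid and ependymal list and 0.62 for the Hox-cluster list, at percentiles 90.24, 96.67 and 67.80, because low-count members drop out. With each replicate left out in turn, detected genes ranged from 425 to 451 and the share of the 10 most abundant genes from 58.6% to 63.5%. Values outside the main results covered single genes, some list values and the shares of the 1 and 25 most abundant genes. Of these, 100 values kept their side of the threshold or moved by less than the replicate spread. Another 33 moved further and 4 lost their call under the negative binomial model. These counts leave out the settings without a replicate, since with 2 replicates a mean cannot move by more than their SD and such settings say nothing about stability. The tally does not measure stability, since a wide spread between the libraries lets a large move stay within it. For example, the mean Mir9 list share went from 0.00628% to 0.00104% with unstranded counts and was among the 100. The count minimum limits what can be said of genes near 10 counts.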

Other observations

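The test in this part was fixed before its result was seen. The margin for calling it undecided was set afterwards, from the counting error of the permutations. Clustered miRNA genes can be cut from a common transcript, so neighbours were expected to differ between the libraries by similar amounts. Over 105 pairs within 10 kb on the same strand, the mean absolute difference of log2 ratios was 0.65, against 1.00 in permutations (one-sided permutation p = 0.0001, the smallest these permutations can give). Without the Mir183 and Mir200 clusters it was 0.65 over 100 pairs against 0.72 (one-sided permutation p = 0.0524), which missed the bound fixed beforehand. The counting interval of that p, 0.0481 to 0.0568, spans 0.05. Without the Dlk1-Dio3 genes as well, p was 0.371 over 54 pairs. Leaving out the Mir183 and Mir200 clusters kept the observed mean at 0.65 and lowered the permuted mean from 1.00 to 0.72. The result over all pairs thus rests on the large ratios of those clusters. Shared transcription or cell source of clustered genes may contribute. Within those clusters the test cannot tell it from other causes that act on them, and beyond them these data do not decide it.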
